A study of Homo sapiens with 45 samples.

How the data were processed

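Total RNA from human skin biopsies was measured on Affymetrix expression arrays, with 1 array per person. The 45 arrays held 18 erythema migrans (EM) lesions, the expanding skin rash of early Lyme disease, 11 samples from healthy volunteers (HV) and 16 surgical control (SC) samples. Per the labels, all SC and 16 EM arrays were batch 1, and all HV and 2 EM arrays were batch 2. The tables place 15 EM and 16 SC arrays on the U133 Plus 2.0 array type and 3 EM and 11 HV arrays on the U133A 2.0 type. EM replicate 16 carried the batch 1 label but lay in the table with batch 2.

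Per the submitters' processing notes, the values came from Affymetrix Expression Console and MAS5, with no versions given. The deposited values were on a log10 scale, as inferred from the values themselves. They ran from 0 to 4.29 with a median of 1.02, and the hybridization spike-ins bioB, bioC, bioD and cre rose with a slope of 1.12 ± 0.05 per log10 amount on the U133 Plus 2.0 type and 1.04 ± 0.05 on the U133A 2.0 type (SD over arrays). The sorted values of any 2 arrays of either table differed by 0, so the tables had been quantile normalized together. The step that gave this normalization and scale was not stated in the notes used here. Values were multiplied by 3.322 to give log2 units, with no further normalization. The lowest spike-in, bioB, lay at 5.88 and 5.76 log2 units on the array types, and fold changes that reach below this level were not calibrated by a known amount. For arrays, the number of arrays limits the precision.

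Both tables held the same 22277 probe sets. Of these, 19071 carried 1 gene symbol, 1043 carried several and 2163 had no symbol or were not listed in the probe table. Of the 1-symbol probe sets, 19059 were matched through the gene identifier and 0 symbols needed an update. The probe set with the highest mean level in the table among those with 1 symbol stood for each gene. The 28 sex-linked genes on the arrays were left out, which left 11935 genes, and those below the 40th percentile of mean level (3.37 log2 units in either table) were not tested. This gave 7161 tested genes per comparison, of which 6970 were tested in both.

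The comparisons were EM against HV (3 and 11 arrays, U133A 2.0) and EM against SC (15 and 16 arrays, U133 Plus 2.0, all batch 1). Each used limma 3.58.1 in R 4.3.3 with linear fits and moderated statistics with an intensity trend, two-sided. Replicates behind every p-value were different people. A gene counted as higher or lower at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a change of at least 2-fold, and these are the thresholds meant throughout. HV and SC were not tested against each other gene by gene because no table holds both. The difference between the comparisons was tested as a contrast of the contrasts in 1 fit with a mean per group and table, an addition made after seeing the data.

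The tests, thresholds, filter, 35 gene lists and the rule for naming genes were set before the data were examined. The lists cover interferon-stimulated genes, antigen presentation, chemokines, cytokines, innate receptors, tryptophan and kynurenine genes, complement, leukocyte markers, keratinocyte and epidermal genes, matrix, vessels, adhesion, lipid synthesis, cell cycle, immediate-early genes, hypoxia and markers of other skin structures. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Lists with fewer than 3 tested members got a count only. The naming rule took the 8 largest higher and 6 largest lower genes per comparison, where EM against HV also required the same sign and at least 50% of the size within batch 2. It added the 2 largest changed members of each main list, 1 of each list of other structures, and CXCL9, CXCL10, CXCL11, IDO1, IFNG and HLA-DRA whatever their values. A further 2 genes of that fixed set are not analysed here. Genes read by probe sets that can match several genes, or of families with closely related members, are marked as uncertain. Probe sets of a gene that share a sign can still differ in size, which this mark does not cover.

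RNA quality was taken as the log2 ratio of 3' to 5' control probe sets of ACTB and GAPDH. List scores were the mean log2 level of a list's genes per array. Groups were compared by permutation tests with 100000 resamples, whose smallest p is 1e-05, or by exact permutation tests when a group had fewer than 10 arrays. All were two-sided. With 3 against 11 arrays there are 364 splits and the smallest exact p is 0.0027. Intervals at the 95% level were t intervals, or inverted exact permutation tests for groups under 10.

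Alternatives changed 1 choice at a time: the level filter, the probe sets per gene, the variance trend, the thresholds, the batch and sample selections, a replicate block, RNA quality and single arrays left out. The exceptions are 2 that left out batch 1 and a further EM array together. The pipeline was tested on simulated data with 7161 genes and 200 changed genes. It recovered 94.0% of changes of 1.5 log2 units in the EM against HV design and 99.0% in the EM against SC design, with 1 and 0 unchanged genes called. The simulated values were independent normal draws with the same SD in both groups. They do not show how the fits behave with correlated genes or a wider spread in EM.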

Results

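Gene expression was measured in skin biopsies from the edge of primary EM lesions of 18 people, in skin of 11 healthy volunteers and in skin from 16 surgical donors, with 1 array per person. The EM samples were split over array types, so that 3 were compared with HV on the U133A 2.0 type and the other 15 with SC on the U133 Plus 2.0 type. The comparisons therefore share no array. The series asks how transcription in the lesion differs from that of normal skin. Levels are in log2 units and changes are EM minus control.

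Among genes that passed the level filter, the most raised transcripts in EM against HV encoded chemokines that draw activated T cells. CXCL10 lay at 13.19 ± 0.64 (SD, n = 3) in EM and 2.61 ± 0.75 (SD, n = 11) in HV, a change of 10.58 ± 0.41 (SE; limma adjusted p = 1.38e-11), and CXCL9 rose by 8.24 ± 0.49. S100A8 and S100A9, which form the antimicrobial protein calprotectin, rose by 6.92 ± 0.77 and 6.03 ± 0.74. S100A8 held the highest value of the normalized scale (14.26) in 1 of the 3 EM arrays and the next value in another. The normalization sets these values by rank, so the size of the S100A8 change is uncertain. The lower of its 2 probe sets changed by 1.21. CCL8, a monocyte-attracting chemokine, rose by 6.21 ± 0.40, the interferon-induced GTPase GBP1 by 5.62 ± 0.28, the soluble pattern-recognition protein PTX3 by 5.45 ± 0.25 and the antiviral gene IFIT3 by 4.92 ± 0.21. All 3 EM arrays exceeded all 11 HV arrays for each of these 8 genes. Genes low in HV could miss the filter and this ranking. Among them were CXCL11 and FPR1, with untested changes of 7.42 and 5.11.

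The lowest transcripts relative to HV included CHP2, a calcium-binding protein, which changed by -3.13 ± 0.32, and KRT15, a keratin of basal and hair follicle bulge cells, by -2.98 ± 0.44. DKK2, a secreted Wnt modulator, changed by -2.75 ± 0.35, the matrix protein POSTN by -2.69 ± 0.37 and the kinase NUAK1 by -2.64 ± 0.23. All 3 EM arrays lay below all 11 HV arrays for these 5 genes. The neuropeptide gene GAL changed by -2.70 ± 0.81 (limma adjusted p = 0.0133), with 2 of 3 EM arrays below all HV. Its change no longer passed without EM replicate 17 (-2.57) or EM replicate 18 (-2.45). The other of the 2 GAL probe sets changed by -0.08.

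In all, 457 genes were higher and 456 lower in EM than in HV among 7161 tested. Within batch 2 (2 EM and 11 HV), 378 were higher and 308 lower, and the CXCL10 change there was 10.42. The third EM array of this comparison carries the label of the other batch, so a batch effect could not be separated from that person. With 3 EM arrays, the precision rests mainly on the HV spread, because the fit takes 1 spread for both groups. Some genes varied more in EM, such as KRT15 (SD 1.74 in EM and 0.37 in HV) and CHP2 (1.22 and 0.29). The SEs and p-values of such genes are too small. Others, such as ATF3 (0.21 and 0.87), varied more in HV.

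**Figure D1:**
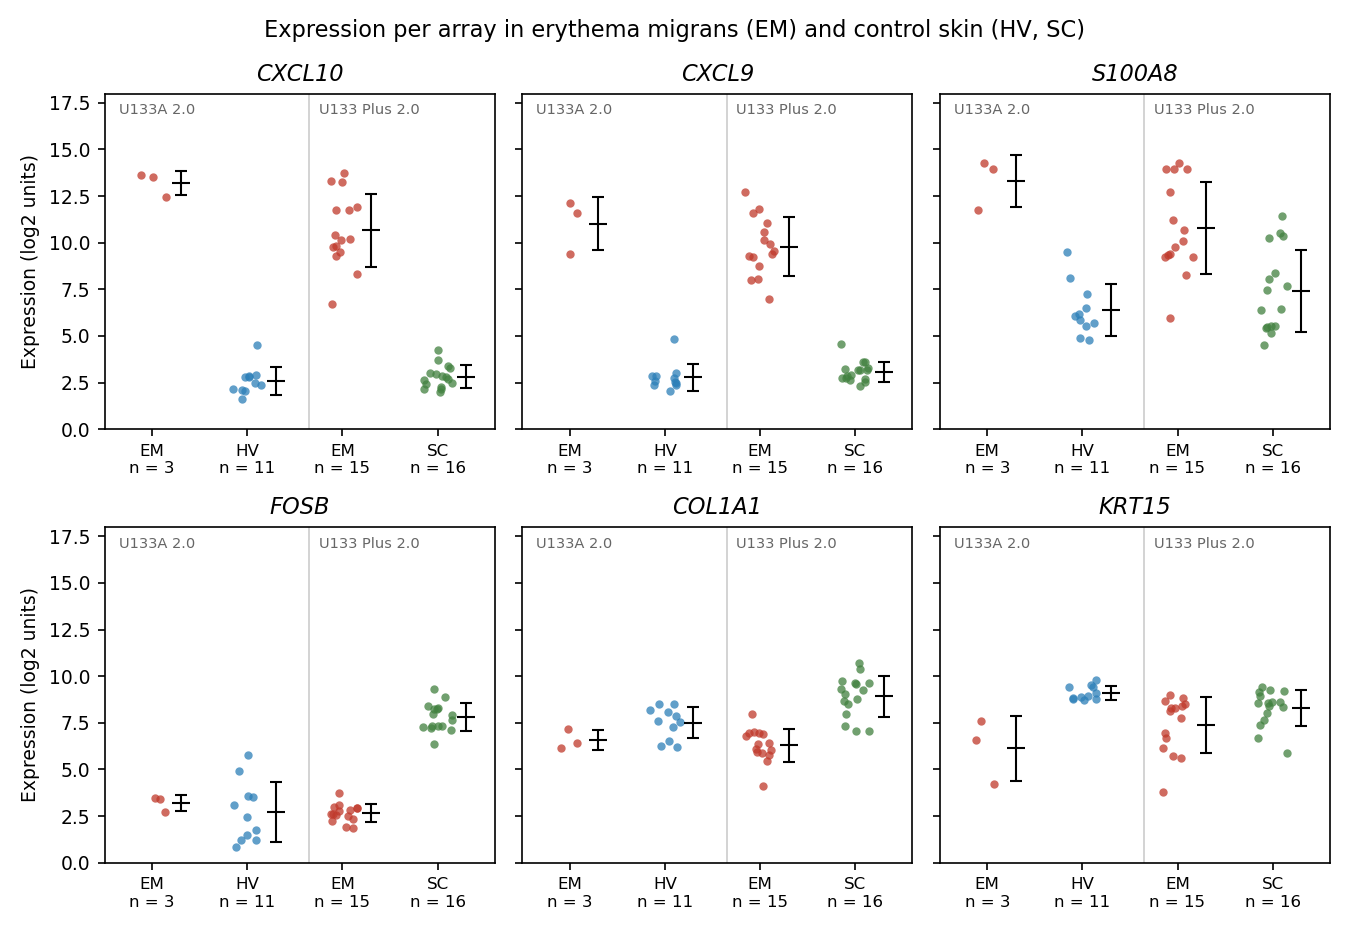
Expression in log2 units per array (points, jittered sideways) of 6 genes in EM and HV on the U133A 2.0 type and in EM and SC on the U133 Plus 2.0 type, with the mean and SD. CXCL10 and CXCL9 were higher in every EM array than in every control array of the same type, and FOSB was lower in all 15 EM arrays than in all 16 SC arrays.

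Interferon-stimulated genes rose as a block against HV. All 27 tested type I interferon-stimulated genes were higher (27 adjusted over the list alone), with a median change of 3.43; the antiviral GTPase MX1 rose by 4.69 ± 0.22. All 14 tested interferon-gamma-responsive genes were higher (14 adjusted over the list alone), with a median of 3.55. Both calls held with an estimated correlation (adjusted p = 0.00729 and 0.0116). The interferon-gamma list shares CXCL9, CXCL10 and other members with the chemokine and antigen-processing lists. It also shares IDO1 and WARS1 with the tryptophan-kynurenine list, so these lists are not separate results. IFNG itself lay below the level filter and was not tested (3.93 ± 1.34 in 3 EM and 1.24 ± 0.71 in 11 HV), as was CXCL11 (8.91 ± 0.99 and 1.49 ± 0.50).

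Of 17 tested MHC class I and antigen processing genes, 9 rose against HV (9 adjusted over the list alone) and 8 did not pass both thresholds, although 14 were higher with no fold limit. The peptide transporter TAP2 rose by 3.26 ± 0.21 and the immunoproteasome subunit PSMB10 by 3.24 ± 0.18. That list's call held with an estimated correlation (adjusted p = 0.0406). For MHC class II presentation, 5 of 11 rose (5 adjusted over the list alone), among them the protease CTSS by 2.50 ± 0.29 and HLA-DRA, a family member and so uncertain, by 1.35 ± 0.25. With EM arrays of both types, added after seeing the data, the HLA-DRA change was 0.68 and did not pass. The class II call was lost with an estimated correlation (adjusted p = 0.242).

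Of 13 tested chemokines, 8 rose (8 adjusted over the list alone) and 5 did not pass both thresholds, of which 1 was lower with no fold limit. The call held with an estimated correlation (adjusted p = 0.0406). Among cytokines, 4 of 8 rose, including the lymphocyte growth factor IL15 by 2.25 ± 0.16 and the death ligand TNFSF10 by 2.30 ± 0.27, and 1 fell, IL18 with -1.47 ± 0.19, named after its value was seen (5 adjusted over the list alone). The cytokine call was lost (adjusted p = 0.0813 with an estimated correlation). Innate receptors and signalling genes had 9 of 14 higher (9 adjusted over the list alone; adjusted p = 0.00729 with an estimated correlation); TLR2 and TLR1, which together sense bacterial lipoproteins, rose by 2.69 ± 0.24 and 2.25 ± 0.24. All 3 tested genes of the tryptophan-kynurenine list rose (3 adjusted over the list alone; adjusted p = 0.0406 with an estimated correlation): IDO1, which starts tryptophan breakdown, by 4.89 ± 0.35, KYNU of the same pathway by 3.08 ± 0.23, and WARS1, which loads tryptophan onto tRNA outside that pathway, by 4.46 ± 0.16. With no level filter, 4 of 7 rose and 1 fell, QPRT (-1.43), named after its value was seen, as was KYNU. Complement genes had 6 of 12 higher (6 adjusted over the list alone), led by the alternative pathway factor CFB at 4.35 ± 0.22 and C1QB at 2.42 ± 0.27. The lower of the 2 CFB probe sets changed by 0.07. The complement call was lost with an estimated correlation (camera adjusted p = 0.194). Leukocyte adhesion molecules had 6 of 9 higher (6 adjusted over the list alone), with the endothelial selectin SELE at 3.83 ± 0.45 and ICAM1 at 3.28 ± 0.24; this call was lost too (adjusted p = 0.109 with an estimated correlation).

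Of 14 tested monocyte and macrophage markers, 9 rose against HV (9 adjusted over the list alone), such as the scavenger receptor CD163 by 2.62 ± 0.18 and the Fc receptor chain FCER1G by 2.67 ± 0.24, and the call was lost with an estimated correlation (adjusted p = 0.109) but held with no level filter (0.0366). Dendritic cell markers moved both ways, with 3 higher, 3 lower and 4 neither of 10 (6 adjusted over the list alone; camera adjusted p = 0.348). LAMP3, found in mature dendritic cells, rose by 2.84 ± 0.24 and the transcription factor BATF3 by 2.18 ± 0.17. The Langerhans and dendritic cell genes CD1E (-1.77 ± 0.39), FCER1A (-1.45 ± 0.24) and CD1A (-1.05 ± 0.23) fell, and were named after their values were seen. Of 4 neutrophil markers, 2 rose (2 adjusted over the list alone; camera adjusted p = 0.103): FCGR3B, uncertain because of its close relative, by 1.46 ± 0.38 and MMP9 by 1.40 ± 0.26. With no level filter the neutrophil list passed (camera adjusted p = 2.07e-05, and 0.00415 with an estimated correlation).

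Few lymphocyte markers were bright enough to test against HV. The T cell list had 1 of 3 higher (2 adjusted over the list alone; camera adjusted p = 0.125), the interleukin receptor IL7R at 1.52 ± 0.47, and it passed as a list without EM replicate 18 (median 1.62) and with EM replicate 16 alone (median 2.28). The T cell median was 1.003 and ran from -0.20 to 2.28 over the EM arrays left out. The cytotoxic list had 2 of 2 higher (2 adjusted over the list alone), the pore-forming PRF1 at 1.37 ± 0.35 and CST7 at 1.01 ± 0.32. None of these 3 genes kept its call without EM replicate 16, where the changes were 0.90, 0.56 and 0.52. GZMB and GZMA lay below the filter and were not tested, with changes of 4.57 and 2.03. With no level filter, 8 of 18 cytotoxic markers were higher than in HV (camera adjusted p = 0.322 with an estimated correlation). The checkpoint list had its only tested gene, CD86, higher by 1.72 ± 0.21 (1 adjusted over the list alone). The single plasma cell gene tested passed neither threshold (0 adjusted over the list alone), and no B cell marker was tested. Of 8 mast cell markers, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.855), the chymase CMA1 by 1.23 ± 0.40, and it no longer passed without EM replicate 17 (1.06) or EM replicate 18 (0.82).

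Keratinocyte activation and antimicrobial genes had 6 higher, 2 lower and 5 neither of 13 against HV (8 adjusted over the list alone; camera adjusted p = 0.0506), led by S100A8 and S100A9, and this list passed without EM replicate 17 (median 0.79) or HV replicate 1 (median 0.60), among other settings. Its median of 0.59 ran from 0.20 to 1.72 over the EM arrays left out. Of 19 epidermal differentiation genes, 4 fell (4 adjusted over the list alone) and 15 did not pass both thresholds, although 10 were lower with no fold limit. The call was lost with an estimated correlation (adjusted p = 0.526). The cornified envelope gene LCE2B (-1.12 ± 0.25), a family member and so uncertain, and the desmosomal DSC1 (-1.11 ± 0.31) were the largest of these. Without EM replicate 16 their changes were -0.64 and -0.46, neither gene passed, and the list with a median of -0.24 had no call. Hair follicle markers had 2 of 6 lower (2 adjusted over the list alone; camera adjusted p = 0.103), with KRT15 the larger, and this list did pass without EM replicate 16 (median -1.74). Sebaceous gland markers had 2 of 3 lower (3 adjusted over the list alone; camera adjusted p = 0.156), GAL and ACSBG1 (-2.44 ± 0.66), the latter named after its value was seen.

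The matrix list had no call against HV. Of 21 extracellular matrix and fibroblast markers, 3 rose, 2 fell and 16 did not pass both thresholds (5 adjusted over the list alone, camera adjusted p = 0.248), with a median of -0.59. With no fold limit, 3 were higher and 7 lower. With EM arrays of both types, a fit added after seeing the data, this list passed as lower (median -0.78), and over the EM arrays left out its median ran from -1.01 to -0.10 without a call. The repair-associated glycoprotein TNC rose by 2.22 ± 0.26 while POSTN fell. Metalloproteinases and their inhibitors had 3 higher and 1 lower of 8 (4 adjusted over the list alone; camera adjusted p = 0.248), with the inhibitor TIMP1 at 2.91 ± 0.24; with no level filter this list passed (adjusted p = 0.0366 with an estimated correlation). Smooth muscle and pericyte markers had 2 of 9 lower (2 adjusted over the list alone; camera adjusted p = 0.127), with the pericyte gene RGS5 at -2.002 ± 0.26. Endothelial markers had 1 higher and 1 lower of 10 (2 adjusted over the list alone; camera adjusted p = 0.709), ENG at 1.18 ± 0.20 (0.535 and not passing with EM arrays of both types) and the tight junction gene CLDN5 at -1.09 ± 0.31, where CLDN5 did not pass without EM replicate 16 (-0.81). Their median (-0.10) and mean (-0.03) were negative where camera's direction was up.

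Immediate-early and heat-shock genes had 4 higher, 1 lower and 10 neither of 15 against HV (5 adjusted over the list alone), with the stress-induced factor ATF3 at 2.16 ± 0.45, and the call was lost with an estimated correlation (adjusted p = 0.484). With EM arrays of both types this list had no call (median 0.08). Melanocyte markers had 1 of 8 lower (1 adjusted over the list alone), the lineage factor MITF at -1.25 ± 0.24, and their call was lost as well (adjusted p = 0.526 with an estimated correlation). Without EM replicate 16, MITF fell just short of 2-fold (-1.0) and the list had no call (median -0.43); without EM replicate 17 the list's median was -0.65 and it had no call. Sterol and fatty acid synthesis had 2 of 14 lower (2 adjusted over the list alone; camera adjusted p = 0.117), the desaturase FADS2 at -1.996 ± 0.53 and the cholesterol enzyme DHCR7 at -1.04 ± 0.34. DHCR7 did not pass without EM replicate 16 (-1.003) or EM replicate 17 (-0.85). Hypoxia genes had 2 higher and 2 lower of 8 (4 adjusted over the list alone; camera adjusted p = 0.855), among the lower EGLN3 at -1.55 ± 0.26 (-0.96 and not passing with EM arrays of both types); their median was -0.32 and mean -0.11 where camera's direction was up. Adipocyte markers had 1 of 3 lower (1 adjusted over the list alone; camera adjusted p = 0.846), CIDEA at -1.49 ± 0.45, whose call was lost without EM replicate 16 at -1.51. In limma, cell cycle genes (0 of 12, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05) and sweat gland markers (0 of 5, 0 adjusted over the list alone, 0 unadjusted, median 1.35) had none past both thresholds, and no skeletal muscle marker was tested. The sweat gland median ran from 0.21 to 2.46 over the EM arrays left out.

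**Figure D2:**
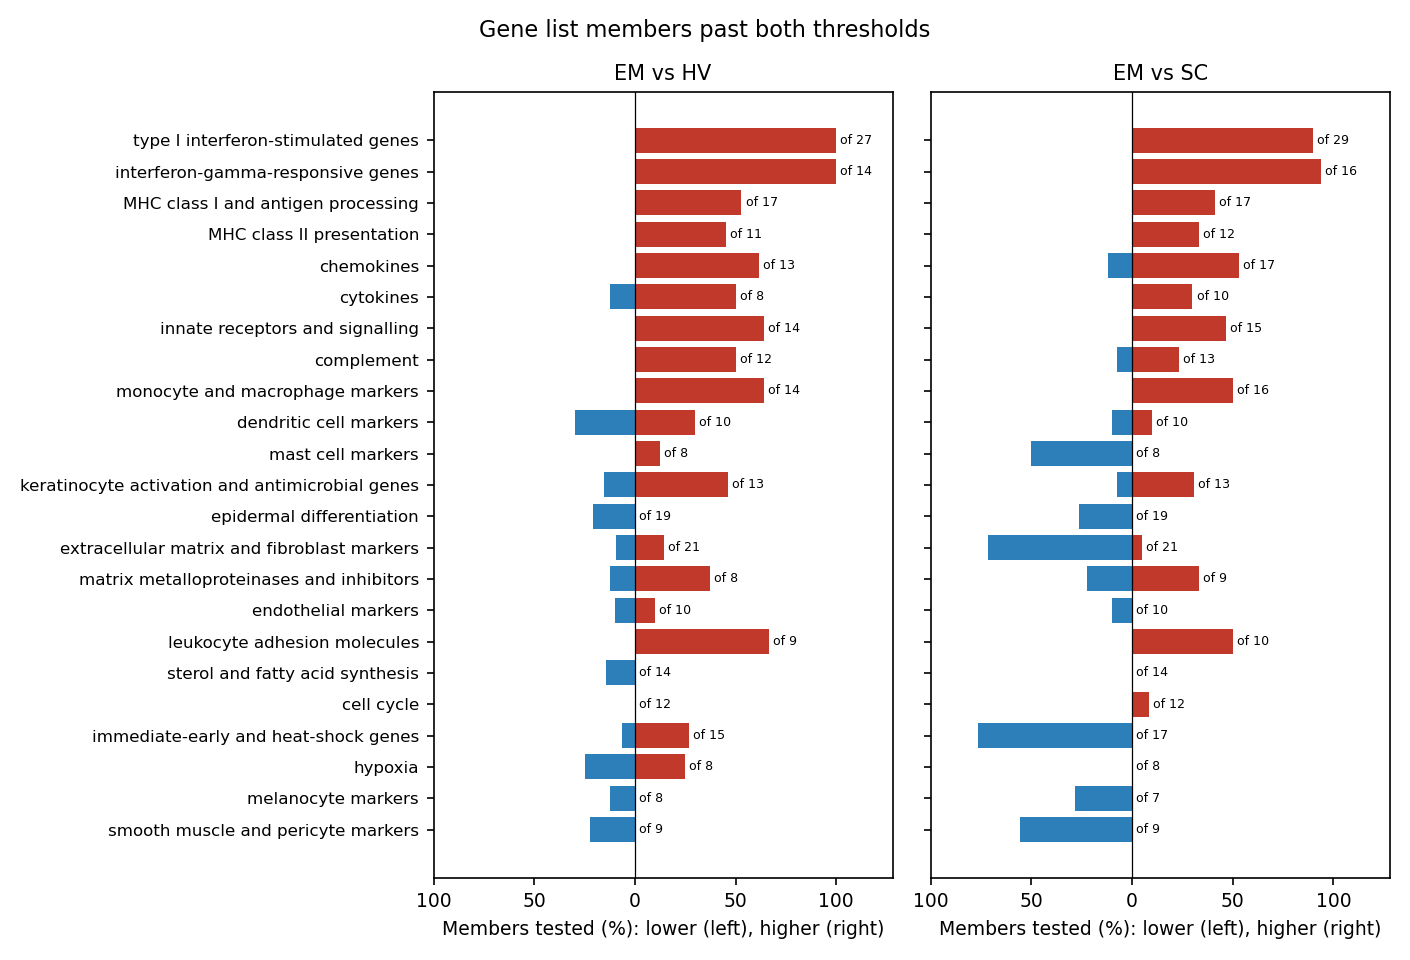
Share of tested list members (percent, horizontal axis) that were higher (right) or lower (left) in EM than in HV or SC, for lists with at least 5 tested members in both comparisons, with the number tested beside each bar. All 27 type I interferon-stimulated genes were higher against HV and 26 of 29 against SC, while 13 of 17 immediate-early and heat-shock genes were lower against SC.

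Against SC, the same chemokine genes led. CXCL10 lay at 10.66 ± 1.95 (SD, n = 15) in EM and 2.82 ± 0.61 (SD, n = 16) in SC, a change of 7.84 ± 0.49 (SE; adjusted p = 3.90e-14). CXCL9 rose by 6.72 ± 0.39 and CXCL11, a ligand of the same receptor, by 5.75 ± 0.35. GBP1 rose by 4.15 ± 0.23, the interferon-induced IFI44L by 3.66 ± 0.35, the cytotoxic granule protease GZMB by 3.39 ± 0.43 and S100A8 by 3.39 ± 0.80. S100A8 lay at the highest value of the scale in 1 EM array and the next in 3, so its size is again uncertain. The lower of its 2 probe sets changed by 1.06. The inhibitory myeloid receptor LILRB2 rose by 4.16 ± 0.49, uncertain because its probe set can match relatives. All 15 EM arrays exceeded all 16 SC arrays for CXCL10, CXCL9, CXCL11, GBP1, IFI44L and LILRB2, 14 did for GZMB and 5 for S100A8.

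Stimulus-induced genes and a collagen were lowest relative to SC. FOSB and FOS, subunits of the transcription factor AP-1, changed by -5.14 ± 0.22 and -4.28 ± 0.25, the MAP kinase phosphatase DUSP1 by -3.01 ± 0.16 and the nuclear receptor NR4A1 by -2.98 ± 0.27. NR4A1 is uncertain, since its probe set can match other transcripts and 2 of its 3 probe sets had the same sign. The fibril-associated collagen COL14A1 changed by -3.20 ± 0.29 and the matricellular CCN5 by -3.09 ± 0.34. Over the 3 COL14A1 probe sets the changes ran from -3.20 to -0.52. All 15 EM arrays lay below all 16 SC arrays for FOSB, FOS, DUSP1, NR4A1 and COL14A1, and 14 did for CCN5.

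Among 7161 genes tested, 278 were higher and 299 lower in EM than in SC, all within batch 1. RNA quality differed between these groups: the 3' to 5' log2 ratio of ACTB was 3.91 ± 0.65 (SD) in EM and 3.38 ± 0.54 in SC (permutation p = 0.0202), and that of GAPDH was 1.25 ± 0.47 and 0.92 ± 0.36 (permutation p = 0.0340). With the ACTB ratio as a covariate, 273 genes were higher and 319 lower. Without the 3 EM arrays whose ACTB ratio exceeded all SC arrays (EM replicates 7, 8 and 11), the counts were 316 and 348. EM and HV did not differ detectably in ACTB (exact permutation p = 0.703) or GAPDH (exact permutation p = 0.692).

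Type I interferon-stimulated genes had 26 of 29 higher than in SC and 3 neither (26 adjusted over the list alone), with a median of 2.31 and IFI44 at 3.03 ± 0.31; interferon-gamma-responsive genes had 15 of 16 higher (15 adjusted over the list alone), with a median of 2.46. Both calls were lost with an estimated correlation (adjusted p = 0.134 and 0.0974), though with no level filter the interferon-gamma call held (0.0339). IFNG was below the level filter (2.60 ± 0.78 in EM and 1.24 ± 0.57 in SC). MHC class I and antigen processing had 7 of 17 higher (7 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation), with TAP2 at 2.39 ± 0.24 and PSMB9 at 2.19 ± 0.22. MHC class II presentation had 4 of 12 higher (4 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation), with CTSS at 2.07 ± 0.30, the class II transactivator CIITA at 1.77 ± 0.26 and HLA-DRA, uncertain as above, at 1.09 ± 0.35.

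The signalling lists moved mostly upward against SC, and none of these calls held with an estimated correlation. Chemokines had 9 higher, 2 lower and 6 neither of 17 (11 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation); the lower ones, named after their values were seen, were the neutrophil attractant CXCL8 (-2.09) and the stromal CXCL12 (-1.09). Cytokines had 3 of 10 higher (3 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation), with TNFSF10 at 1.83 ± 0.17 and IL15 at 1.60 ± 0.16; this list had no call without EM replicate 13 (median 0.54). Innate receptors and signalling had 7 of 15 higher (7 adjusted over the list alone, camera adjusted p = 0.211 with an estimated correlation), with the formyl peptide receptor FPR1 at 2.98 ± 0.47 and TLR2 at 1.94 ± 0.32. The other of the 2 FPR1 probe sets changed by 0.30. The tryptophan-kynurenine list had 3 of 3 higher (3 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation), with WARS1 at 2.73 ± 0.29 and IDO1 at 2.66 ± 0.41. Adhesion molecules had 5 of 10 higher (5 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation), with VCAM1 at 1.97 ± 0.21 and ITGB2 at 1.81 ± 0.34. Complement had 3 higher and 1 lower of 13 (4 adjusted over the list alone, camera adjusted p = 0.179), with CFB at 2.86 ± 0.34 and CFD, a serine protease of the same pathway, at -1.63 ± 0.32. The lower of the 2 CFB probe sets changed by 0.41.

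Of 4 cytotoxic and NK cell markers tested against SC, 3 rose (3 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation), GZMB, GZMA (1.89 ± 0.40) and PRF1. Of 16 monocyte and macrophage markers, 8 rose (8 adjusted over the list alone; adjusted p = 0.530 with an estimated correlation); AIF1 rose by 1.92 ± 0.37, uncertain because 3 of its 4 probe sets had the same sign. T cell markers had 1 of 4 higher (1 adjusted over the list alone; camera adjusted p = 0.0763), CD2 at 1.06 ± 0.29, and without EM replicate 13 that list passed (median 1.04). CD86 again rose as the only tested checkpoint gene, by 1.12 ± 0.28 (1 adjusted over the list alone). Neutrophil markers had 4 higher and 1 lower of 6 (5 adjusted over the list alone; camera adjusted p = 0.0865), with FPR1 and the iron-binding LTF (2.03 ± 0.51). Dendritic cell markers had 1 higher and 1 lower of 10 (2 adjusted over the list alone; camera adjusted p = 0.896), LAMP3 at 1.86 ± 0.24 and CD1C at -1.10 ± 0.26. Mast cell markers had 4 of 8 lower (4 adjusted over the list alone; camera adjusted p = 0.0834), among them the tryptases TPSAB1 (-1.28 ± 0.26) and TPSB2 (-1.25 ± 0.27), uncertain because they share sequence. The single plasma cell gene tested passed neither threshold (0 adjusted over the list alone), and no B cell marker was tested.

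The immediate-early and heat-shock list had the lowest median change against SC. Of 17 members, 13 were lower and 4 neither (13 adjusted over the list alone), with a median of -1.92, and this was the only call of EM against SC that held with an estimated correlation (adjusted p = 0.0441). The list score was 5.89 ± 0.31 (SD) in EM and 7.80 ± 0.34 in SC, with no overlap between the 15 and 16 arrays. The EM arrays also had the higher ACTB 3' to 5' ratio (by 0.53), and with that ratio as a covariate the score difference was -1.88 ± 0.13 (SE) instead of -1.90 ± 0.12.

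Collagens and other matrix genes were lower in EM than in SC. Of 21 extracellular matrix and fibroblast markers, 15 fell, 1 rose and 5 did not pass both thresholds (16 adjusted over the list alone), although 17 were lower with no fold limit. COL3A1, at the highest value of the scale in 1 SC array, changed by -2.66 ± 0.43 and COL1A1 by -2.61 ± 0.34. Over 4 probe sets each, the changes ran from -2.66 to -0.05 for COL3A1 and from -2.92 to -0.34 for COL1A1. The riser, named after its value was seen, was TNC at 1.03. The call was lost with an estimated correlation (adjusted p = 0.288). EM replicate 13 had the lowest matrix score (4.44, against 7.44 for the lowest SC array), and without it 287 genes were higher and 254 lower. The groups' ACTB ratios differed by 0.53 here too, and the score difference was -1.43 ± 0.25 (SE) with that covariate and -1.39 ± 0.22 without. Smooth muscle and pericyte markers had 5 of 9 lower (5 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation), with the contractile gene CNN1 at -2.04 ± 0.56. Their score varied widely in SC, from 5.21 to 8.85, and 3 of 15 EM arrays lay below all SC arrays for CNN1. Metalloproteinases and inhibitors had 3 higher and 2 lower of 9 (5 adjusted over the list alone; camera adjusted p = 0.896), with the macrophage elastase MMP12 at 2.44 ± 0.31 and TIMP3 at -2.13 ± 0.32; their mean was 0.09 where the median (-0.03) and camera's direction were negative. Endothelial markers had 1 of 10 lower (1 adjusted over the list alone; camera adjusted p = 0.661), CLDN5 at -1.07 ± 0.22, which no longer passed without EM replicate 13 (-0.99).

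Epidermal differentiation had 5 of 19 lower against SC (5 adjusted over the list alone; adjusted p = 0.562 with an estimated correlation), with the cornified envelope proteins LCE2B, uncertain as above, at -1.45 ± 0.45 and LORICRIN at -1.43 ± 0.41. Keratinocyte activation and antimicrobial genes had 4 higher and 1 lower of 13 (5 adjusted over the list alone; camera adjusted p = 0.603), with S100A8 and S100A9 (2.65 ± 0.68) highest; the median was -0.03 where the mean (0.63) and camera's direction were positive. Cell cycle genes had 1 of 12 higher (1 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation), the mitotic kinase CDK1 at 1.09 ± 0.22, which did not reach 2-fold with the ACTB covariate (0.86). Melanocyte markers had 2 of 7 lower (3 adjusted over the list alone; camera adjusted p = 0.0763), with the pigment protein PMEL at -1.59 ± 0.47. Hair follicle markers had 1 of 3 lower (1 adjusted over the list alone; camera adjusted p = 0.247), KRT31 at -1.29 ± 0.25. In limma, sterol and fatty acid synthesis (0 of 14), hypoxia (0 of 8), sweat gland (0 of 4), sebaceous gland (0 of 3) and adipocyte markers (0 of 2) had none past both thresholds and 0 adjusted over the list alone. At an unadjusted p under 0.05 these lists had 5, 6, 0, 0 and 0 genes. The hypoxia median was -0.20 and mean -0.03 where camera's direction was up. No skeletal muscle marker was tested.

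Many of the same genes passed in both comparisons, which use different people throughout. Of 6970 genes tested in both, 455 were higher against HV, 255 were higher against SC and 198 were higher against both, where 16.6 would be shared if the calls were independent (Fisher's exact p = 1.28e-199). For lower genes the numbers were 447, 287 and 114, with 18.4 expected (Fisher's exact p = 1.64e-64). Both Fisher tests take genes as independent units, which co-regulated genes are not, so their p-values do not measure replication over people. Across genes, which are not independent replicates, the changes correlated with Pearson r = 0.703 and Spearman rho = 0.631. The 198 shared higher genes had a median change of 2.27 against HV and 1.49 against SC.

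The genes that differed most between the comparisons were immediate-early genes. In the contrast of the contrasts, 162 of 7161 genes changed more positively against HV than against SC and 101 more negatively, past both thresholds. Of 17 immediate-early and heat-shock genes, 12 were among the former (12 adjusted over the list alone; adjusted p = 0.000738 with an estimated correlation). FOS changed by 0.61 ± 0.91 against HV (limma adjusted p = 0.617), which did not pass, and fell against SC. Chemokines (5 of 16) and cytokines (3 of 10) also kept their call of a larger change against HV with an estimated correlation (adjusted p = 0.0283 each; 6 and 3 adjusted over the list alone). The interferon lists did not, with 4 of 29 type I and 6 of 16 interferon-gamma-responsive genes past both thresholds (7 and 9 adjusted over the list alone; adjusted p = 0.332 and 0.277 with an estimated correlation). Opposite calls were found for 9 genes higher against HV and lower against SC, which were CCN1, JUNB, ZFP36, TNFAIP3, ATF3, COMP, PTGIS, ACKR3 and RGS1, and for GOLGA8A in the other sense. If the calls were independent, 18.7 and 16.4 such genes would be expected, so opposite calls were fewer than that. The genes with opposite calls were named after their values were seen, except ATF3.

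**Figure D3:**
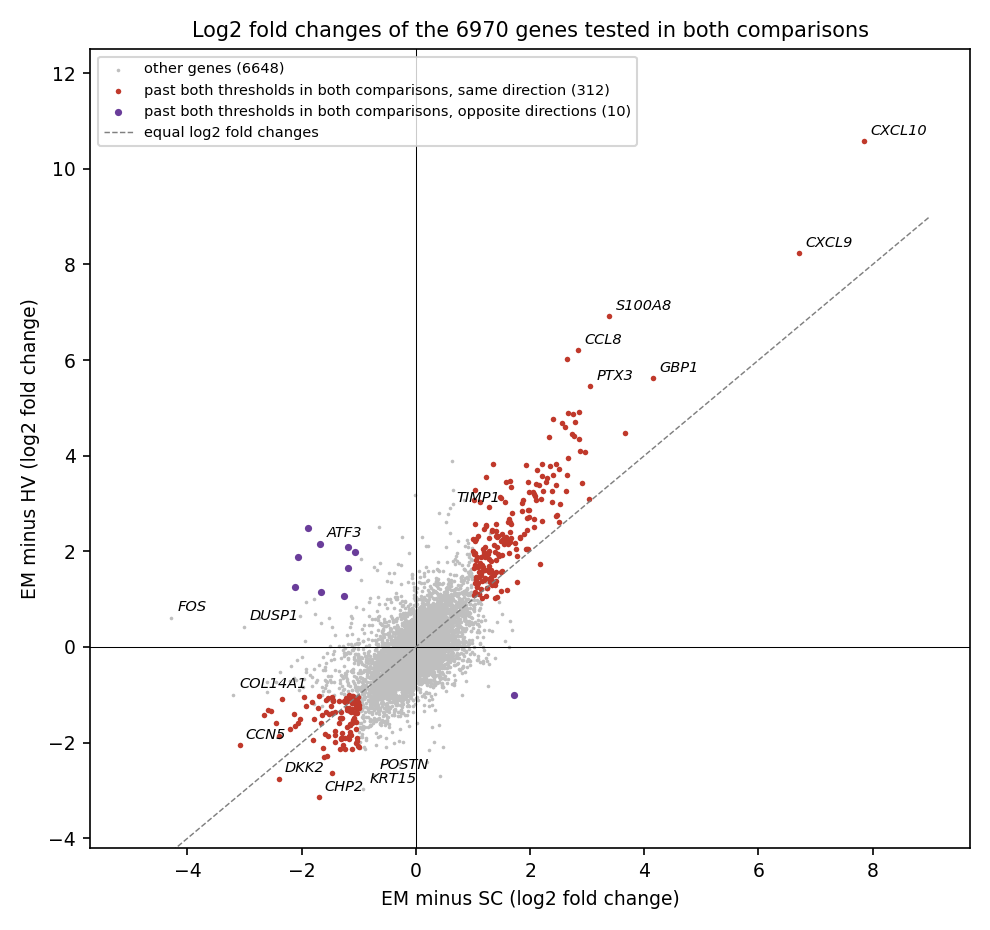
Log2 fold changes of the 6970 genes tested in both comparisons, EM minus SC (horizontal) and EM minus HV (vertical), where each point is a gene and the dashed line marks equal changes. Genes past both thresholds in the same direction (198 higher and 114 lower) and in opposite directions are coloured, and FOS and DUSP1 lie left of zero with values of 0.61 and 0.43 against HV.

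**Figure D4:**
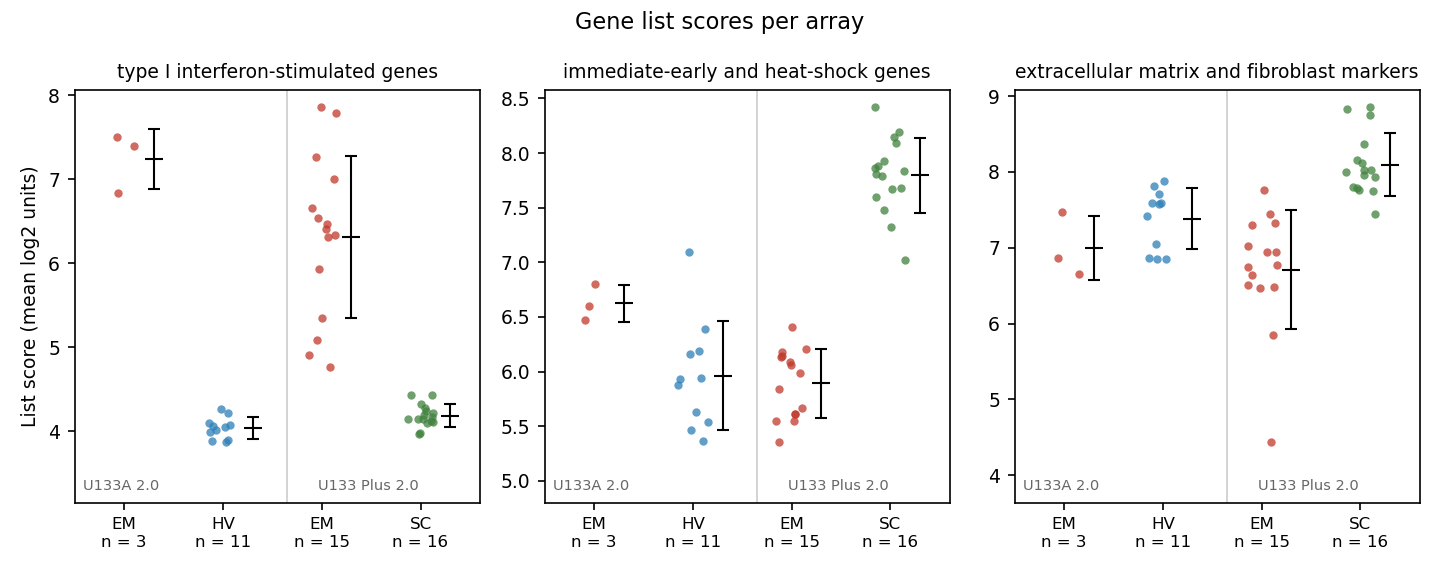
List scores (mean log2 level of the list's genes) per array as points, with mean and SD, for type I interferon-stimulated, immediate-early and heat-shock, and matrix genes in each group of each array type. The interferon score of each EM array lay above every control array of its type, and the immediate-early score of the 16 SC arrays averaged 7.80, against 5.96 in 11 HV arrays on the other array type.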

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

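The contrast between the comparisons, the tests of a lesion change, surgical collection, dilution (first on endothelial markers, then on epidermal genes), less dermis, a lower HV level and stronger lesions, and the fits with the ACTB ratio as a covariate were chosen only after the result they bear on was seen. What singled out the 17 genes of this part was a difference between the EM against HV and the EM against SC changes that passed a test, out of 83 named genes tested. Each value is the change against HV minus the change against SC in log2 units, from the joint fit, where the probe set of a gene can differ from that of a single comparison. The comparisons differ in people, array type and batch, so a difference may reflect any of these. The array types were joined only by a shared normalization. Poly-A control spikes, added before labelling, ran from 6.55 to 9.76 log2 units on U133 Plus 2.0 and from 3.32 to 3.92 on U133A 2.0. Spike use or labelling may thus differ too, which also limits the scores compared across array types. With EM arrays of both types against HV, 251 genes were lower instead of 456.

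Grouping by chance was put to a test for both counts. For EM against HV, 1 of 100 splits of the arrays, the real one, gave as many as 913 genes, and the highest of the other splits gave 49. For EM against SC the real split gave 577 genes, again 1 of 100, and the highest other gave 0. Chance assignment of arrays to groups is argued against for both counts, at the resolution of 100 splits. The other splits place EM arrays in both groups, which widens the spread and lowers their own counts.

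Immediate-early genes made up 5 of the 17. The differences were 5.63 for FOSB, 4.89 for FOS, 3.84 for ATF3, 3.44 for DUSP1 and 3.42 for NR4A1, the last uncertain because its probe set can match other transcripts. All but ATF3 passed only as lower against SC, and ATF3 was also higher against HV. FOSB and NR4A1 lay below the level filter against HV.

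The fall of the immediate-early list against SC was weighed against 3 explanations. A lesion change that lowers these genes against any normal skin is argued against by the EM minus HV score of 0.66 (95% interval 0.02 to 1.29, exact permutation p = 0.041), which is on the other side of 0. A difference in RNA quality is argued against as the whole cause, since the score difference was -1.88 with the ACTB covariate and -1.90 without. For a rise in SC through surgical collection, the score was 1.83 higher in SC than in HV (95% interval 1.47 to 2.20). This cannot single out collection, because any cause of a higher SC level gives the same result. The EM minus SC and EM minus HV scores, seen before, also largely set it. Although 95% of random gene lists of matched level differed by less than 0.20, this does not bound an offset in 1 co-regulated list. EM arrays of the U133A 2.0 type scored 0.73 above the other EM arrays in this list. SC and HV are wholly separated by array type and batch, so collection, array type, batch, donors and body site all stay open.

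COL14A1 was the only matrix structural gene of the 17, with a difference of 2.20: it fell by 3.20 against SC and its change against HV was -0.998 and did not pass. TIMP1 differed by 2.31.

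For the fall of the matrix list against SC, dilution by infiltrating cells could not be settled: it would lower epidermal genes alike, and the matrix minus epidermal differentiation score differed by -0.735 (95% interval -1.44 to -0.026), but by -0.553 (-1.18 to 0.075) without EM replicate 13. The matrix minus endothelial score differed by -1.26 (-1.60 to -0.92), on endothelial markers near the low end of the scale. The matrix minus smooth muscle score differed by -0.14 (-0.97 to 0.69). This score cannot decide, because it ran from -0.971 to 2.815 in SC (SD 1.445), against -0.078 to 2.146 in EM. Less dermis in the EM biopsies would raise epidermal genes, but the mean epidermal differentiation score was lower too, at -0.65 (-1.13 to -0.17). A loss of epidermal transcripts in the lesion could still hide a small rise. The mean also hides a spread in EM from 6.03 to 9.26. EM replicates 7, 10 and 11 (9.08, 9.26 and 8.86) lay above the SC mean of 8.845, and the other EM arrays of this type lay below it. The matrix scores of EM replicates 7, 10 and 11 (6.74, 6.95 and 6.48) lay below the lowest SC array (7.44). They lay near the mean of the 15 EM arrays (6.71), so they do not single out these 3. EM replicates 12 and 13 were the 2 lowest EM arrays of this type in matrix (5.85 and 4.44), endothelial (3.54 and 2.86) and smooth muscle scores (4.475 and 3.61). Their epidermal differentiation scores were 8.07 and 8.47. Less dermis in some EM biopsies stays open. RNA quality as the whole cause is argued against by a score difference of -1.43 with the ACTB covariate. What also stays open is a fall in the lesion and a higher level in SC skin, since the matrix score of SC was 0.72 above that of HV across array types and the EM minus HV difference was -0.39 (exact permutation p = 0.18).

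The other 10 genes were all higher in EM than in HV, by more than against SC. The chemokines CCL8 and CXCL10 differed by 3.37 and 2.74. The interferon-responsive IFIT3, MX1, WARS1 and GBP1 differed by 2.06, 2.13, 1.73 and 1.47. The remaining values were 2.40 for PTX3, 2.13 for ICAM1, 1.26 for BATF3 and 1.26 for PSMB10.

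The interferon lists changed more against HV by a median of 1.11 (type I) and 1.32 (interferon-gamma), calls that were lost with an estimated correlation (adjusted p = 0.332 and 0.277), and 2 explanations were weighed. A lower level of these genes in HV than in SC skin is argued against only if both array types read this list alike. The type I interferon score of HV was -0.15 relative to SC (95% interval of SC minus HV 0.04 to 0.25), against a gap of 1.08 between the comparisons. That contrast crosses array types. Although 95% of random gene lists of matched level differed by less than 0.14, this does not bound an offset in 1 co-regulated list. Stronger lesions among the 3 EM of the HV table could not be settled: their type I score was 0.93 above that of the other 15 (95% interval -0.31 to 2.19, exact permutation p = 0.12). Their interferon-gamma score was 1.19 above (0.004 to 2.38, exact permutation p = 0.048), which goes with stronger lesions, but 95% of random gene lists of matched level differed by up to 0.22 in the same contrast, more than the lower end. These 3 lesions and the array type cannot be told apart, because no HV or SC sample was run on both types.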

How the results depend on the processing

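The ACTB covariate, the arrays left out singly (EM replicates 16, 17 and 18 within all EM, and arrays picked by RNA quality or matrix score) and the fit with EM arrays of both types were chosen after seeing the data. All 4 counts kept within 1.5 times their value with no level filter (645 higher and 524 lower against HV, 360 and 329 against SC), with the mean of all probe sets, with an adjusted p under 0.01, without the variance trend and with the ACTB covariate. Without the filter, the lists of T cell, neutrophil, keratinocyte activation, metalloproteinase, sterol, sebaceous gland, hair follicle and smooth muscle genes gained a call against HV, and those of T cell, neutrophil and melanocyte genes against SC. With an estimated correlation only the neutrophil (adjusted p = 0.00415) and metalloproteinase (0.0366) lists against HV kept these gained calls. Lists with too few tested members under the filter passed camera as well. They were the cytotoxic (adjusted p = 3.12e-05) and checkpoint (0.0152) lists against HV and the checkpoint list against SC (0.0128). None of these passed with an estimated correlation (0.322, 0.109 and 0.234). A filter at the 60th percentile, which tests fewer genes, left 261 higher against HV and 164 higher against SC, and ended the calls of the cytokine list in both comparisons and of the epidermal differentiation and melanocyte lists against HV. With no fold limit, which adds small changes, 1213 were higher and 1818 lower against HV, and 1674 and 1822 against SC.

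Leaving out EM arrays moved the count against HV between 318 and 602 for higher and between 215 and 756 for lower genes. Both ends came from a single EM array left, assumed to vary like the HV arrays: EM replicate 17 alone gave the lowest counts and EM replicate 16 alone, the batch 1 array, the highest. With 2 EM arrays left, the counts reached at most 500 higher and 588 lower, without EM replicate 17. EM arrays of both types gave 334 higher and 251 lower, and HLA-DRA, CST7, CMA1, DSC1, ENG, CLDN5 and EGLN3 lost their calls; the cause was not tested. The median of the melanocyte list ran from -1.74 to 0.20 over the arrays left out, with -1.38 without EM replicate 18, and reversed without batch 1 and EM replicate 17. Averaging probe sets took ENG and DHCR7 below 2-fold against HV and CD86, TPSAB1 and CDK1 against SC, and all EM arrays against SC (298 higher, 294 lower) did so for CD1C and CDK1. With the replicate number as a block (replicate block), EM against SC gave 281 higher and 297 lower, and only the cytokine list lost its call. The numbers do not pair people: same-number pairs correlated from -0.31 to 0.22 (median -0.01, 4 of 15 over 0.1), and 0 EM arrays correlated best with their own number. For EM against HV, no paired analysis was possible because the groups share no replicate numbers.

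Not run were pseudocounts and quantile normalization, which the deposited scale made void, a joint fit of all samples of a table and each table alone, which equal the fits reported, leaving out each sample in turn for EM against SC, whose groups are larger, and HV against SC. Low signals limit the arrays: with no filter, 8 of 18 cytotoxic markers rose in either comparison, against 2 and 3 with it, and values below the lowest spike-in were not calibrated.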

Other observations

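The test of each relation with the interferon-gamma score was set before its result was seen, and the genes of the next paragraphs were picked after their values were seen, as was the HV array left out at the end. DBP, PER3 and NR1D2 were lower in both comparisons. They act in the circadian clock, for which no gene list was tested, and the clock genes CLOCK, BMAL1, NPAS2 and CRY1 passed in neither comparison. DBP changed by -2.29 ± 0.22 against HV and -1.56 ± 0.20 against SC, PER3 by -1.10 ± 0.30 and -1.57 ± 0.17, and NR1D2 by -1.02 ± 0.36 and -1.11 ± 0.31 (each past both thresholds). PER2 and CRY2 fell past both thresholds against SC (-1.57 ± 0.13 and -1.30 ± 0.16), while against HV their changes of -0.71 and -0.82 did not reach 2-fold. TSC22D3, a glucocorticoid-induced gene, fell in both (-1.23 ± 0.25 and -1.92 ± 0.26), as did the insulin receptor substrates IRS2 (-1.79 ± 0.19 and -1.30 ± 0.20) and IRS1 (-1.37 ± 0.17 and -1.31 ± 0.15).

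The metallothionein genes MT1M, MT2A and MT1H, whose proteins bind zinc and copper, rose against HV and not detectably against SC. MT1M changed by 3.90 ± 0.26 and 0.64 ± 0.42 (adjusted p of the difference 0.00425), MT2A by 2.29 ± 0.17 and 0.10 ± 0.25 (0.00139) and MT1H by 1.96 ± 0.24 and -0.12 ± 0.21 (0.000736). MT2A and MT1H are uncertain because their probe sets can match relatives. Further secreted and inflammatory genes rose in both comparisons: the phospholipase PLA2G2A by 4.88 ± 0.44 and 2.76 ± 0.44, the trypanolytic lipoprotein APOL1 by 4.70 ± 0.26 and 2.79 ± 0.32, and the lymphoid chemokine CCL19 by 4.11 ± 0.34 and 2.87 ± 0.34.

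Lymphocyte genes too dim for the level filter were counted without it. Of 17 T cell markers, 4 were then higher against HV and 2 against SC, of 11 B cell markers 0 (limma, 2 at an unadjusted p under 0.05) and 1, and of 10 plasma cell markers 1 and 2. Of 15 neutrophil markers, 8 were higher against HV, and 6 were higher and 1 lower against SC.

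The interferon-gamma score of the 15 EM lesions on the U133 Plus 2.0 type ranged from 5.54 to 8.92, and 3 relations with other measures were computed as hypotheses of this re-analysis. Cytotoxic cells might vary with it: the cytotoxic score gave Pearson r = 0.395 (permutation p = 0.15, adjusted 0.41) and Spearman rho = 0.246 (0.38, adjusted 0.56), and r = 0.244 without the 2 lesions farthest from the median. Matrix genes might fall with it: r = -0.306 (permutation p = 0.27, adjusted 0.41) and rho = -0.296 (0.28, adjusted 0.56), with r = -0.354 without those 2. RNA quality might vary with it: r = -0.150 (permutation p = 0.59, adjusted 0.59) and rho = -0.071 (0.80, adjusted 0.80), with r = -0.491 without those 2. None passed, and the 95% intervals of r were -0.146 to 0.755 for the cytotoxic score, -0.707 to 0.245 for the matrix score and -0.615 to 0.392 for RNA quality, so each of the 3 relations stays open.

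The poly-A control spikes, which are added to the RNA before labelling, lay between 6.55 and 9.76 log2 units on the 31 arrays of the U133 Plus 2.0 type and between 3.32 and 3.92 on the 14 of the U133A 2.0 type. EM replicate 16, labelled batch 1, read 3.47 and so lay with the latter. In RNA quality, HV replicate 1 had the highest ACTB 3' to 5' log2 ratio of the HV arrays (6.50, with the next at 4.72); without it, 462 genes were higher and 461 lower against HV.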
